A study of Arabidopsis thaliana with 28 samples.

How the data were processed

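Transcripts were measured by RNA sequencing in 28 libraries of Arabidopsis thaliana seedlings. Per the labels, the plants were 12 days old, grown in long days at 21 °C after 4 days of stratification at 4 °C. The 6 genotypes had 3 libraries each and grew on soil; the Mock and TSA groups had 5 libraries each of Col-0 in medium with sucrose. The deposited gene tables hold raw read counts, one table for the 18 genotype libraries and one for the 10 Mock and TSA libraries, and another deposited table holds raw counts over 31189 TEs in the genotypes. The tools the authors used to align and count the RNA reads are not given in the sources used here; the processing they describe is that of their ChIP-seq data, on the TAIR10 genome. The authors' comparison tables give log2 fold changes and adjusted p-values per the file headers, and the tool behind them is not named; they were read as a side check only. In the authors' deposited tables, 428 genes were higher and 18 lower in hda6-1, 597 and 459 in hda9-1, 152 and 132 in h2a.z-5, and 4094 and 3937 in TSA. Gene names and gene types came from a TAIR10.1 annotation, in which all 36632 gene identifiers were found; its coordinates served only to find the genes next to HDA6. The design text of the series names nrp1-1 nrp2-2 where the sample labels name h2a.z-5, and the labels were followed.

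Gene counts summed to between 32795474 and 39633678 per genotype library and between 30257874 and 40395659 per Mock or TSA library. TE counts summed to between 300951 and 484606, so that changes in TEs were measured less precisely. The reads carry no molecular identifiers, so floors cover counting error only. The exact intervals for shares of genes and Fisher's exact tests treat the genes as independent draws. They cover neither counting error nor the spread between libraries.

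Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test, two-sided, with TMM scaling. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 20771 genes in the genotypes, 20201 in Mock and TSA, and 1786 TEs. TE counts were scaled by the effective library sizes of the gene table. The genotype contrasts were fitted together on all 18 libraries (12 residual degrees of freedom), and TSA against Mock on 10 (8 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. There were 12 gene contrasts and 7 TE contrasts. Log2 fold changes are edgeR's, with standard errors from the fit, and group values are means and SD of CPM (counts scaled to a common library size). Ratios of single libraries are log2 of CPM with 0.5 CPM added to each value. Where a group had no count, a fold is given as at least the ratio to a floor of 3 counts over that group, and where it had 1 to 3 counts only the levels are given.

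A total of 20 gene lists with 315 members were fixed in advance. They hold target and histone variant genes, SWR1 and INO80 complex subunits, histone deacetylases and acetyltransferases, flowering time genes, salicylic acid defence genes, jasmonate genes, heat shock genes, cold and drought response genes, phosphate starvation genes, anthocyanin and flavonoid genes, photosynthesis genes, seed maturation genes, floral organ identity and meristem genes, silenced loci, senescence genes, xenobiotic response genes, auxin response genes, cell cycle genes, circadian clock genes and root markers. They were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists within a contrast. The directional test fry was used for the set of genes raised by TSA, and overlaps were tested with Fisher's exact test, two-sided, over genes tested in both tables.

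The contrasts, the lists and the rule for named genes were chosen before the data were examined. The rule takes the target genes in every sample. It takes genes called with a mean of at least 1 CPM and every library of one group beyond every library of the other: the 8 largest changes each way for h2a.z-5, hda6-1 and hda9-1 against Col-0 and TSA against Mock, and 4 for other contrasts. It takes up to 4 called members with the smallest p of each list that passed or had at least 1 in 4 of its tested members called, and of TEs the 5 largest rises and 3 largest falls in each single mutant. Members of other lists with few calls, the genes of the interaction counts, the genes shared by 5 mutants and the clock genes of replicate 5 were chosen after their values were seen.

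Replicate numbers were checked for pairing before blocked calls were compared. After removal of group means, libraries of the same number correlated at 0.142 to 0.647 over the 45 pairs of genotype libraries and at 0.101 to 0.496 over the 5 pairs of Mock and TSA libraries, against medians of -0.240 and 0.0326 for pairs of different numbers. The numbers thus pair the samples. The gene, TE and list tests, the sets raised and lowered by TSA, the overlaps with TSA and the shares were run again with replicate number as a block. The fits without single libraries, the tests of gene types, the splits and the genes chosen anew had no block. A call lost without a library there need not be lost in a blocked fit.

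Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a minimum log2 fold change of 1, a fit on the groups of the contrast only, the replicate block, leaving out each library in turn, TMM from the TE counts and an estimated correlation. Added after the data were seen were Mock and TSA replicates 1 to 4 only, a run without rRNA genes, TEs up to the point where the counts of hda6-1 replicate 1 end, a TE fit that leaves this library out, protein-coding genes only, list tests without Col-0 replicate 3 and without hda9-1 h2a.z-5 replicate 3, splits of the interactions within replicate numbers, a block for the set lowered by TSA, and simulated data with effects of the replicate numbers. The pipeline was tested on simulated data: of genes changed 4-fold it called 74.2% at the design of the genotypes, 42.4% at that of TSA and 56.1% for TEs, and of genes changed 2-fold 38.8%, 4.48% and 10.4%. It made 4, 3 and 1 false calls. The 5 deposited comparison tables for TEs were left out: in 2 of them the header is shifted by a column, and the TE counts were tested directly.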

Results

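RNA was sequenced from Arabidopsis thaliana seedlings, 12 days old, in 28 libraries. The series asks how acetylation of histone H3 relates to the placing of the histone variant H2A.Z by the SWR1 remodelling complex. The libraries bear on the transcripts that change when histone deacetylases are lost or inhibited and when H2A.Z is lost. The wild type Col-0, the H2A.Z mutant h2a.z-5, the deacetylase mutants hda6-1 and hda9-1, and the crosses hda6-1 h2a.z-5 and hda9-1 h2a.z-5 had 3 libraries each, grown on soil. Col-0 seedlings in medium with the deacetylase inhibitor trichostatin A (TSA) and in medium without it (Mock) had 5 libraries each. The series text calls the replicates independent biological replicates. Gene counts summed to between 32795474 and 39633678 per library in the 18 genotype libraries and to between 30257874 and 40395659 in the 10 Mock and TSA libraries. Counts over transposable elements (TEs), given for the genotypes only, summed to between 300951 and 484606 per library. In what follows, "edgeR adjusted p" stands for the p of edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment within a contrast, and "camera adjusted p" for that of a list test with a preset correlation. Lists that passed only with replicate number as a block, or only without single libraries or replicate 5, did not pass there with an estimated correlation (adjusted p of 0.107 or more). Named TEs and pseudogenes can share reads with genes that overlap them, and the strand of the counts is not stated.

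HTA8, HTA9 and HTA11, which encode H2A.Z proteins, were low in every library whose label carries h2a.z-5. HTA11 (AT3G54560) was at 61.4 ± 9.06 CPM (counts scaled to a common library size, SD, n = 3) in Col-0, 1.64 ± 0.387 CPM in h2a.z-5, 2.71 ± 0.728 CPM in hda6-1 h2a.z-5 and 1.04 ± 0.361 CPM in hda9-1 h2a.z-5. HTA9 and HTA8 fell less far: HTA9 (AT1G52740) from 144 ± 9.19 CPM to 52.5 ± 4.43 CPM and HTA8 (AT2G38810) from 16.9 ± 1.91 CPM to 6.07 ± 0.897 CPM in h2a.z-5. HTA4, an H2A.Z gene at 1.098 ± 0.601 CPM in Col-0 and 0.971 ± 0.210 CPM in h2a.z-5, did not pass (edgeR adjusted p = 0.988). HDA9 (AT3G44680) was at 13.9 ± 1.71 CPM in Col-0, 1.62 ± 0.111 CPM in hda9-1 and 1.01 ± 0.367 CPM in hda9-1 h2a.z-5. HDA6 (AT5G63110) did not follow its labels in the same way: it stood at 16.7 ± 3.40 CPM in Col-0, at 128 ± 28.3 CPM in the libraries labelled hda6-1 and at 16.9 ± 1.07 CPM in the libraries labelled hda6-1 h2a.z-5. NRP1 and NRP2, which encode histone chaperones, passed the test in none of the 12 gene contrasts.

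**Figure D1:**
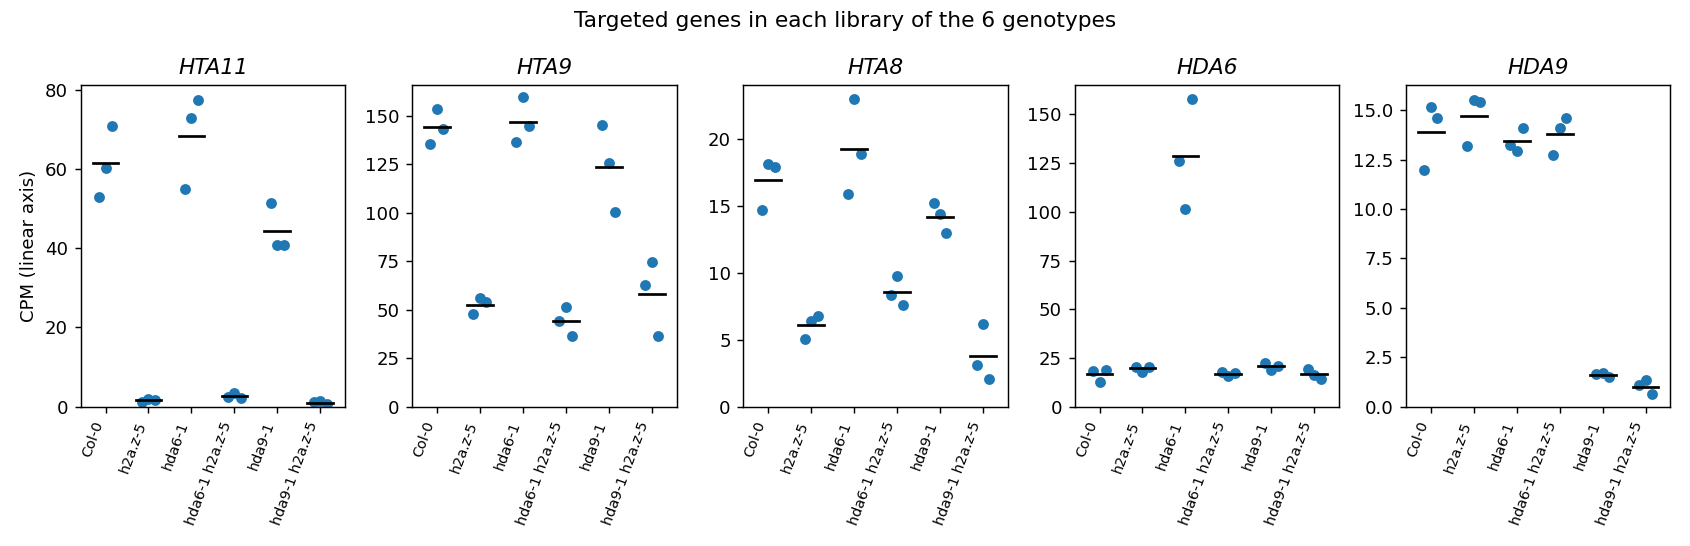
CPM (linear axis) of 5 targeted genes in each library of the 6 genotypes; points are libraries and bars are means of 3. HDA6 lies above 100 CPM in the 3 libraries labelled hda6-1 only, and HTA11 is at most a few CPM in every library with h2a.z-5 in its label.

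The contrast of h2a.z-5 with Col-0 asks which transcripts depend on H2A.Z. The genes with the largest rises included AGO5 (AT2G27880), which encodes an Argonaute protein, at 6.29 ± 1.42 CPM against 0.0959 ± 0.0308 CPM, and AGO9 (AT5G21150), another Argonaute gene, at 2.94 ± 1.06 CPM against 0.317 ± 0.169 CPM (SD, n = 3). AT1G75945 rose from 0.0624 ± 0.0369 to 17.0 ± 3.83 CPM, and AT2G25330 stood at 2.43 ± 0.644 CPM against 1 count in Col-0. The noncoding RNA gene AT3G05945 fell from 23.0 ± 0.518 to 0.629 ± 0.114 CPM, AT5G05060 fell from 28.6 ± 2.87 to 2.12 ± 0.152 CPM, and SADHU5-1, a retroelement-like locus, fell from 29.0 ± 6.22 to 1.40 CPM. AT2G04070 had no count in h2a.z-5 and was at least 93.5-fold lower. The log2 fold change was -5.22 ± 0.28 (SE) for HTA11 (edgeR adjusted p = 1.36e-08) and 5.96 ± 0.57 for AGO5 (edgeR adjusted p = 2.33e-05). It was -1.45 ± 0.22 for HTA9 (edgeR adjusted p = 0.00225) and -1.48 ± 0.28 for HTA8 (edgeR adjusted p = 0.0146). The HTA8 call was lost without Col-0 replicate 2 (edgeR adjusted p = 0.0561) or 3 (0.0589) and without h2a.z-5 replicate 1 (0.0944) or 2 (0.0549). Of 15 flowering time genes tested, 2 rose (AP1 and FUL) and 1 fell (MAF4), against 3 and 3 adjusted over the list alone; none of the 3 kept the call whichever library was left out, with edgeR adjusted p of up to 0.181. The list of floral organ identity and meristem genes passed the list test (camera adjusted p = 0.000944) with a median log2 fold change of 0.72, though not with an estimated correlation (adjusted p = 0.611). Of its 11 members tested, SEP2 rose, and 4 rose and 1 fell adjusted over the list alone; the SEP2 call was lost without Col-0 replicate 2 (edgeR adjusted p = 0.0990) or 3 (0.117) and without h2a.z-5 replicate 1 (0.0961). HDA18, the member called among 20 histone deacetylase and acetyltransferase genes, rose by 1.55 ± 0.24 log2 units. Seed maturation genes (3 tested), xenobiotic response genes (15) and cell cycle genes (12) had no member called in either way; their medians were 0.90, -0.44 and 0.22, their camera adjusted p 0.0367, 0.0367 and 0.0403, and adjusted p = 0.319, 0.721 and 0.721 with an estimated correlation, and with replicate number as a block the camera adjusted p was 0.0762 for each. Without Col-0 replicate 3, an alternative chosen after the data were seen, it was 0.0687 for seed maturation and 0.266 for cell cycle genes, and 0.00331 for jasmonate genes, against 0.830 with this library. The target genes had 3 members lower in both ways (camera adjusted p = 5.51e-12). This list holds the genes targeted in the mutant lines, so its tests between genotypes check the lines and say nothing of other genes. In all, 109 genes were higher and 80 lower of 20771 tested. The total of 189 was 785 with replicate number as a block. It was 96 and 95 without Col-0 replicates 2 and 3, and 102, 114 and 108 without h2a.z-5 replicates 1, 2 and 3.

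The libraries labelled hda6-1 were compared with Col-0 to ask which transcripts change with the loss of the deacetylase HDA6, known for the silencing of repeats. Nearly all changes were rises, many of them at loci with no count in the 3 Col-0 libraries. AT1G53810, AT4G07965, AT2G04320 and AT5G27947 were at least 1814-fold, 1739-fold, 1365-fold and 1323-fold higher. AT2G15555 stood at 248 ± 36.9 CPM (SD, n = 3) against 2 counts in Col-0. Of 8 silenced loci 2 were tested, and both rose. QQS, a gene known for epigenetic variation between plants, was at 45.6 ± 8.36 CPM against 2.52 ± 0.761 CPM (log2 fold change 4.17 ± 0.39, edgeR adjusted p = 3.67e-06). The retrotransposon gene ATLINE1-4 was at least 224.5-fold higher, and passed the filter only through libraries with hda6-1 in the label. These 2 were also called adjusted over the list alone (camera adjusted p = 2.81e-11). HDA6 itself rose by 2.94 ± 0.19 log2 units (edgeR adjusted p = 1.13e-07). Among the 21 genes that fell were BBX18, a zinc finger regulator of light responses, at 36.6 ± 8.45 CPM against 81.5 ± 7.84 CPM, and AG, which specifies stamens and carpels, at 0.273 ± 0.0559 CPM against 1.72 ± 0.170 CPM. AG was the member called of 11 tested genes for floral organs and meristems, and also the member called adjusted over the list alone (camera adjusted p = 0.0167, and adjusted p = 0.850 with an estimated correlation). MAF4, a repressor of flowering, rose by 2.06 log2 units and COR15B, a cold-induced gene, by 1.31 log2 units. Of the 613 genes that rose, 178 are annotated as pseudogenes (29.0%, against 1.43% of all genes tested, Fisher exact p = 9.57e-201). The total of 634 genes was 1005 with replicate number as a block. Without each library in turn it stayed between 551 and 592. The list of heat shock genes, with a median log2 fold change of 0.77, had camera adjusted p = 0.0885 in the test without a block and 0.00679 with it; that of the target genes had 0.0634 and 0.0123.

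TEs showed the same direction in the libraries labelled hda6-1: 274 were higher and 9 lower of 1786 tested. AT1TE70815 was at 298 ± 119 CPM (SD, n = 3) against 1 count in the Col-0 libraries, and AT1TE42875 was at 296 ± 98.5 CPM against 0.0480 CPM. AT3TE48070 and AT3TE53580 had no count in Col-0 and were at least 909.0-fold and 629.6-fold higher. AT5TE36335 was at least 914.1-fold higher, but had no count in hda6-1 replicate 1, and with replicate number as a block its edgeR adjusted p was 0.108. Its call was also lost without Col-0 replicates 1 (edgeR adjusted p = 0.0757), 2 (0.0713) and 3 (0.0753) and without hda6-1 replicates 2 (0.0602) and 3 (0.0516). AT4TE10625 fell by 2.56 log2 units (edgeR adjusted p = 7.95e-05) and AT4TE10320 by 2.72 log2 units (edgeR adjusted p = 0.00124). In hda6-1 replicate 1, none of the 7134 TEs after AT4TE59920 in the table, which include those of chromosome 5, had a count, while 1119 and 1120 of them had in replicates 2 and 3. The test kept this library, so these zeros entered it as counts. AT5TE36335 is among these TEs, so its lack of counts in replicate 1 is no evidence of absence. The mean behind its fold includes that zero. Its call was kept without hda6-1 replicate 1. Without the library, 339 TEs were higher and 10 lower of 1895 tested, and 58, 83, 83, 44 and 71 of the higher lay on chromosomes 1 to 5; this tally was chosen after the data were seen.

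**Figure D2:**
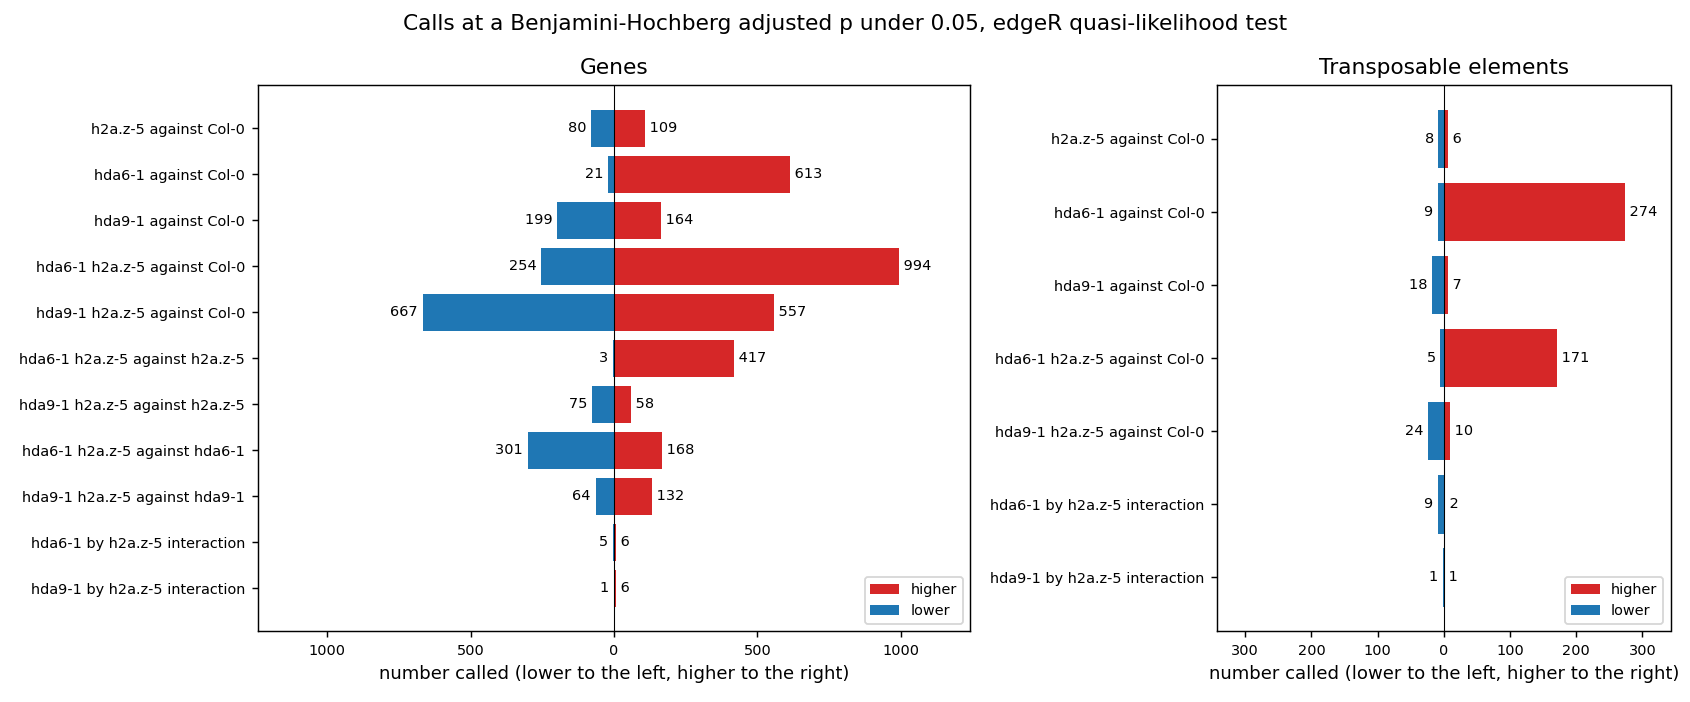
Numbers of genes (left) and TEs (right) called higher (red, to the right of 0) and lower (blue, to the left of 0) in each genotype contrast, at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. In the libraries labelled hda6-1 against Col-0, 613 genes were higher and 21 lower.

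The hda9-1 libraries were compared with Col-0 for the deacetylase HDA9, which is known from work on flowering and leaf ageing. Here about as many genes fell as rose. AT1G75945 rose to 16.0 ± 2.52 CPM (SD, n = 3) from 0.0624 ± 0.0369 CPM in Col-0, and AT3G21030 and AT5G62280 rose by 2.72 ± 0.30 and 2.82 ± 0.42 log2 units (SE). MES18, which encodes a methylesterase, fell from 36.7 ± 10.5 to 7.19 ± 2.41 CPM, and XTH19, a gene for a cell wall enzyme, fell from 9.64 ± 2.56 to 2.46 ± 0.463 CPM. HDA9 fell by 3.10 log2 units (edgeR adjusted p = 5.55e-07), and was the target gene called of 8 (camera adjusted p = 8.50e-05, and adjusted p = 0.0548 with an estimated correlation). None of 24 salicylic acid defence genes was called over all genes and 11 rose adjusted over the list alone, with a median log2 fold change of 1.12 (camera adjusted p = 1.61e-10). With an estimated correlation the list did not pass (adjusted p = 0.165). Of 12 senescence genes, NAP, a transcription factor gene of leaf ageing, rose by 2.52 log2 units, and 2 rose adjusted over the list alone (camera adjusted p = 0.000109, and adjusted p = 0.120 with an estimated correlation). The NAP call was lost without Col-0 replicate 1 (edgeR adjusted p = 0.0644) or 2 (0.0892) and without hda9-1 replicate 1 (0.0572) or 2 (0.0550). Of 8 auxin response genes, GH3.5 rose by 1.49 log2 units, and 2 rose adjusted over the list alone (camera adjusted p = 0.00546, and adjusted p = 0.0548 with an estimated correlation). The GH3.5 call was lost without Col-0 replicate 1 (edgeR adjusted p = 0.0521) or 2 (0.0815) and without hda9-1 replicate 1 (0.0570). Of 17 jasmonate genes none was called in either way (median log2 fold change 0.62, camera adjusted p = 0.0387, and adjusted p = 0.882 with an estimated correlation). The jasmonate genes of Col-0 replicate 3 lay 2.31 log2 units above those of the other Col-0 replicates; without this library, an alternative chosen after the data were seen, the median was 2.05 (camera adjusted p = 1.43e-07). The flowering repressors MAF4 and MAF5 fell by 1.49 and 2.51 log2 units, the members called of 15 flowering time genes, against 1 higher and 2 lower adjusted over the list alone. Both lost the call without single libraries, with edgeR adjusted p of up to 0.183 and 0.119. In all, 164 genes were higher and 199 lower. The total of 363 was 3392 with replicate number as a block. It was 80 and 53 without Col-0 replicates 1 and 2, and 133, 63 and 101 without hda9-1 replicates 1, 2 and 3.

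The libraries labelled hda6-1 h2a.z-5 were compared with Col-0 and with each parent label, to ask what the joint loss changes. Against Col-0, loci silent in the wild type again rose: AT5G41660 stood at 121 ± 30.2 CPM (SD, n = 3) against 3 counts, and AT1G49090 and AT4G07526 were at least 413.3-fold and 152.8-fold higher. HTA11 fell by 4.50 ± 0.27 log2 units (edgeR adjusted p = 7.03e-08) and HTA9 by 1.71 ± 0.22. HTA8 was also called, at a log2 fold change of -0.98 (edgeR adjusted p = 0.0434), and this call was lost without Col-0 replicate 1 (edgeR adjusted p = 0.0591), 2 (0.117) or 3 (0.118) and without hda6-1 h2a.z-5 replicate 1 (0.134), 2 (0.0612) or 3 (0.153). Target genes thus counted 3 lower over all genes and 3 adjusted over the list alone (camera adjusted p = 8.16e-08). HDA6 was not called, at a log2 fold change of 0.02 (edgeR adjusted p = 0.978). Of 15 flowering time genes, FUL, LFY and AP1, which act in floral transition, rose and FLC, a repressor of flowering, fell, against 3 and 3 adjusted over the list alone. FUL was at 13.5 ± 0.701 CPM against 6.39 ± 0.701 CPM, and LFY rose by 2.00 ± 0.37 log2 units. AP1 lost the call without Col-0 replicate 3 (edgeR adjusted p = 0.0543), and FLC without Col-0 replicate 2 (0.0970) and hda6-1 h2a.z-5 replicates 1 (0.1001) and 3 (0.0800). Of 15 heat shock genes, HSP18.2, HSP17.6C and HSP17.6II rose, 4 adjusted over the list alone (camera adjusted p = 0.00344, and adjusted p = 0.791 with an estimated correlation). HSP18.2 was at 8.73 ± 1.68 CPM against 2.42 ± 0.295 CPM, and the HSP17.6II call was lost without Col-0 replicates 2 (edgeR adjusted p = 0.0505) and 3 (0.0764). QQS and ATLINE1-4, the silenced loci tested, both rose (camera adjusted p = 9.59e-07); QQS stood at 27.8 ± 5.63 CPM, and ATLINE1-4, at least 29.7-fold higher, lost the call without Col-0 replicate 3 (edgeR adjusted p = 0.0538). SEP2 was higher and AG lower of 11 floral organ and meristem genes, against 4 and 1 adjusted over the list alone (camera adjusted p = 0.0426, 0.0751 without Col-0 replicate 3, and adjusted p = 0.791 with an estimated correlation). Both calls were lost without single libraries, with edgeR adjusted p of up to 0.169 for SEP2 and 0.0751 for AG. Against Col-0, 994 genes were higher and 254 lower. The total of 1248 was 2988 with replicate number as a block and 825 without Col-0 replicate 3.

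Against h2a.z-5, the libraries labelled hda6-1 h2a.z-5 had 417 genes higher and 3 lower. QQS rose from 0.749 ± 0.116 to 27.8 ± 5.63 CPM (SD, n = 3, log2 fold change 5.21 ± 0.42, edgeR adjusted p = 1.80e-06), AT3G01345 from 0.0990 ± 0.0591 to 437 ± 57.2 CPM, and AT1G62460 was at least 644.6-fold higher. The 3 lower genes were AT5G38010, GIS and LARP6b, and each lost the call without at least 5 of the 6 libraries taken singly, with edgeR adjusted p of up to 0.253, 0.225 and 0.1503. QQS and ATLINE1-4 made up the silenced loci tested (camera adjusted p = 2.69e-16). Of 15 heat shock genes, HSP17.6C and HSP23.6 rose, and 4 adjusted over the list alone (camera adjusted p = 0.00962, and adjusted p = 0.935 with an estimated correlation). The HSP17.6C call was lost without h2a.z-5 replicate 1 (edgeR adjusted p = 0.108), 2 (0.0887) or 3 (0.0571). The HSP23.6 call was lost without h2a.z-5 replicate 1 (edgeR adjusted p = 0.106), 2 (0.0866) or 3 (0.129) and without hda6-1 h2a.z-5 replicate 1 (0.105), and that of ATLINE1-4 without 5 of the 6 libraries, at 0.0757 to 0.109. The total of 420 was 671 with replicate number as a block, and 248, 269 and 256 without h2a.z-5 replicates 1, 2 and 3. Against hda6-1, 168 genes were higher and 301 lower, and 106 of the lower ones are pseudogenes. AP1 rose by 5.49 ± 0.72 log2 units (edgeR adjusted p = 0.000311), LFY by 2.37 ± 0.38 and FUL by 1.53 ± 0.15, while MAF4 fell from 12.7 to 2.43 CPM and FLC by 3.47 log2 units. With FT, whose call was lost without 5 single libraries at edgeR adjusted p of up to 0.203, 4 flowering time genes were higher and 2 lower of 15, and 4 and 3 adjusted over the list alone. AP3, SEP2 and SEP3 rose of 11 floral organ and meristem genes, and 9 adjusted over the list alone (camera adjusted p = 3.42e-10, and adjusted p = 0.164 with an estimated correlation). AP3 lost the call without hda6-1 replicate 3 (edgeR adjusted p = 0.0613), SEP2 without hda6-1 replicates 1 (0.0742) and 2 (0.0776) and hda6-1 h2a.z-5 replicate 1 (0.0795), and SEP3 without 5 of the 6 libraries, at up to 0.274. Target genes counted 4 lower in both ways (camera adjusted p = 1.51e-22): HTA11, HTA9, HDA6, which fell by 2.92 ± 0.19, and HTA8, whose call was lost without 5 of the 6 libraries, at 0.0523 to 0.141. Photosynthesis genes (median log2 fold change -0.23) and cell cycle genes (0.27) had no member called in either way; their camera adjusted p was 0.00914 and 0.0144, and adjusted p = 0.750 for both with an estimated correlation. The silenced loci had camera adjusted p = 0.0242, and adjusted p = 0.252 with an estimated correlation, with 1 member lower adjusted over the list alone; with replicate number as a block the camera adjusted p was 0.0690. The total of 469 was 1049 with replicate number as a block, 290 and 306 without hda6-1 h2a.z-5 replicates 1 and 3, and 302 without hda6-1 replicate 3.

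Of the 613 genes higher in the libraries labelled hda6-1 than in Col-0, 306 were also higher in the libraries labelled hda6-1 h2a.z-5 than in h2a.z-5 (49.9%, exact 95% interval 45.9% to 53.9%), against 2.01% of all genes tested. These contrasts share no library. The share was 33.6%, 34.1% and 34.4% without h2a.z-5 replicates 1, 2 and 3 and 42.4%, 39.6% and 39.3% without hda6-1 h2a.z-5 replicates 1, 2 and 3, where fewer libraries were tested, and the log2 fold change was positive for 95.1% of the 613. For 322 of these genes, each of the 4 groups held over 3 counts. Of them, 274 had a smaller log2 fold change on the h2a.z-5 background, with a median of 1.46 against 2.06. HDA6 itself differed between the libraries labelled hda6-1 and hda6-1 h2a.z-5, so the smaller change cannot be assigned to the loss of H2A.Z. The genes were also chosen for their rise in the first contrast, which favours a smaller value in the second. Genes were also chosen anew in some of the libraries (367 to 426 genes, with no minimum count) and measured in others, which avoids this choice. The values were log2 ratios of CPM in single libraries with 0.5 CPM added to each value, not edgeR's fold changes. The added 0.5 CPM shrinks ratios at low counts, so they are not on the scale of the medians of 1.46 and 2.06. The median difference was -0.96 ± 0.07 (mean and SD over 3 runs). It was -0.69 ± 0.08 for protein-coding genes and -1.32 ± 0.07 for pseudogenes. The interaction test, which asks of each gene whether the change with hda6-1 differs between the backgrounds, called 6 genes higher and 5 lower, and 323 passed an unadjusted p of 0.05. Higher were AT3G05945 (4.53 ± 0.29, edgeR adjusted p = 3.99e-07), AT3G05955, AT3G29120, AT1G18193, AT2G04080 and SADHU5-1, and lower were AT1G75945 (-8.21 ± 0.46, edgeR adjusted p = 8.51e-08), HDA6 (-3.15 ± 0.26, edgeR adjusted p = 8.65e-06), AT1G45063, AT3G29633 and AT1G67105. AT3G05945 and AT3G05955 were low in h2a.z-5 and stood at 11.03 ± 1.81 and 7.33 ± 4.06 CPM in the libraries labelled hda6-1 h2a.z-5 (SD, n = 3). The AT1G67105 call was lost with replicate number as a block (edgeR adjusted p = 0.0734) and without 9 of the 12 libraries taken singly (up to 0.276, without h2a.z-5 replicate 2). With the block, 12 genes were higher and 6 lower. Of the lists, the target genes (1 lower in both ways, camera adjusted p = 1.51e-05) also passed with an estimated correlation (adjusted p = 0.0337). The member called was HDA6 itself. Floral organ and meristem genes (median 0.63) and photosynthesis genes (median -0.28) both had camera adjusted p = 3.35e-05 with no member called, and adjusted p = 0.419 and 0.550 with an estimated correlation. The jasmonate list had a median of 0.97 (camera adjusted p = 0.0201, and adjusted p = 0.713 with an estimated correlation), and of -0.46 (camera adjusted p = 0.127) without Col-0 replicate 3, where these genes were high. The flowering time list had camera adjusted p = 0.0833, and 0.0413 with the block.

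**Figure D3:**
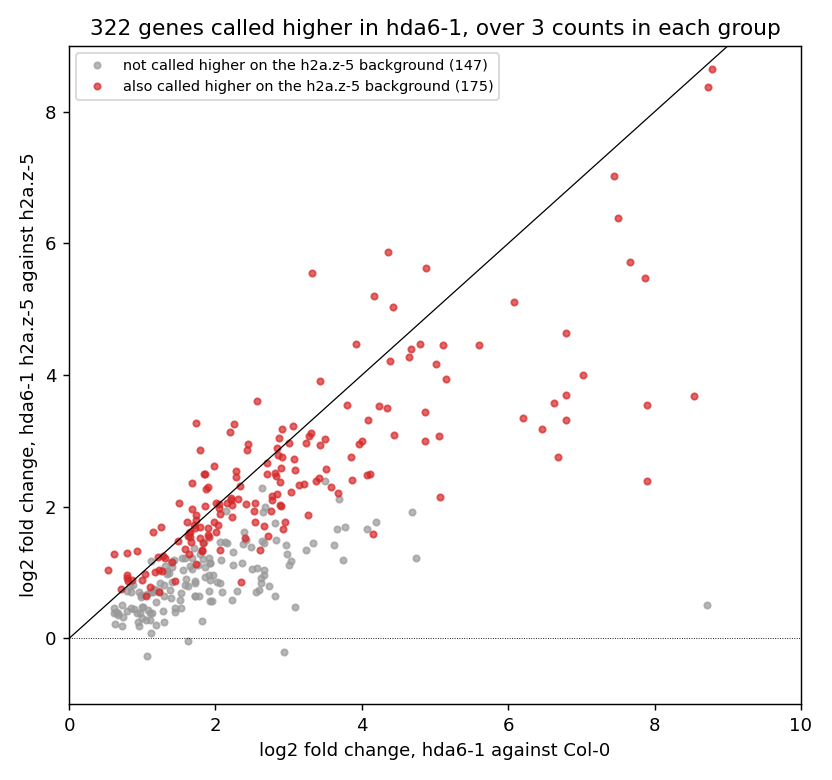
Log2 fold change in the libraries labelled hda6-1 against Col-0 (x axis) and in those labelled hda6-1 h2a.z-5 against h2a.z-5 (y axis) for the 322 genes higher in the first contrast with over 3 counts in each group; the solid line marks equal values. Red points (175 genes) were also called higher in the second contrast, and 274 points lie under the line. The genes were chosen for their rise on the x axis, which favours points under the line.

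The hda9-1 h2a.z-5 libraries were compared in the same way. Against Col-0, HTA11 fell by 5.89 ± 0.30 log2 units (edgeR adjusted p = 7.80e-09), HDA9 by 3.79 ± 0.21, HTA8 by 2.16 ± 0.29 and HTA9 by 1.31 ± 0.21, so that 4 of 8 target genes fell and 5 adjusted over the list alone (camera adjusted p = 8.50e-22). AT4G18900 rose from 0.0435 to 8.46 ± 2.58 CPM (SD, n = 3), AT2G25330 stood at 4.11 ± 0.922 CPM against 1 count, and SADHU5-1 fell by 7.19 ± 0.53 log2 units (edgeR adjusted p = 8.26e-07). Of 15 flowering time genes 3 rose (AGL19, AP1 and LFY) and 3 fell (MAF4, MAF5 and FLC), against 5 and 4 adjusted over the list alone. AGL19 (2.55 ± 0.46), MAF4 (-2.91 ± 0.40) and MAF5 (-4.00 ± 0.61) kept the call whichever library was left out; AP1, LFY and FLC did not, with edgeR adjusted p of up to 0.0705, 0.105 and 0.0702. Auxin response genes had 3 members higher of 8, and 4 adjusted over the list alone, and passed with both correlations (camera adjusted p = 6.42e-05, and adjusted p = 0.00543 with an estimated correlation). GH3.5, an auxin-conjugating enzyme gene, rose by 1.92 ± 0.27 and IAA1 by 1.86 ± 0.33; the IAA29 call was lost without single libraries, with edgeR adjusted p of up to 0.122. NAP, at 12.9 ± 6.35 CPM against 1.495 ± 0.650 CPM, and SAG29 were the senescence genes called of 12, against 4 adjusted over the list alone (camera adjusted p = 0.0309, and adjusted p = 0.675 with an estimated correlation); SAG29 lost the call without Col-0 replicates 2 (edgeR adjusted p = 0.0550) and 3 (0.0671), and the list did not pass without hda9-1 h2a.z-5 replicate 3 (camera adjusted p = 0.137), an alternative chosen after the data were seen. SWC6, a subunit of the SWR1 complex, fell by 0.95 log2 units (edgeR adjusted p = 0.00364). HTA4 was called with replicate number as a block (edgeR adjusted p = 0.0171) and not without it. The heat shock list, with no member called in either way, had camera adjusted p = 0.240, and 0.0101 with replicate number as a block; the floral list had 0.0822 and 0.0407. The jasmonate list (0.804) passed with a median log2 fold change of 1.59 without Col-0 replicate 3 (0.00314) and of -1.52 without hda9-1 h2a.z-5 replicate 3 (0.0351), so that its direction hangs on single libraries. In all 557 genes were higher and 667 lower. The total of 1224 was 4922 with replicate number as a block. It was 800, 591 and 419 without Col-0 replicates 1, 2 and 3, and 803 and 783 without hda9-1 h2a.z-5 replicates 1 and 3.

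Against h2a.z-5, the hda9-1 h2a.z-5 libraries had 58 genes higher and 75 lower. HDA9 fell by 3.87 ± 0.21 log2 units (edgeR adjusted p = 7.32e-08), XTH19 fell from 15.8 ± 0.633 to 3.67 ± 0.744 CPM (SD, n = 3), and QQS rose from 0.749 ± 0.116 to 6.58 ± 0.765 CPM. AT3G29120 rose from 0.444 ± 0.132 to 6.26 ± 0.821 CPM. GH3.5 was the member called of 8 auxin response genes, against 5 adjusted over the list alone (camera adjusted p = 4.56e-08, and adjusted p = 0.00112 with an estimated correlation), and its call was lost without 5 of the 6 libraries, with edgeR adjusted p of up to 0.158. Xenobiotic response genes had 0 of 15 called and 5 higher adjusted over the list alone (camera adjusted p = 2.65e-05, and adjusted p = 0.197 with an estimated correlation). Salicylic acid defence genes had 0 of 24 called in either way (camera adjusted p = 0.000334, adjusted p = 0.581 with an estimated correlation, and camera adjusted p = 0.165 without hda9-1 h2a.z-5 replicate 3). NAP rose of 12 senescence genes (camera adjusted p = 0.00134, and adjusted p = 0.190 with an estimated correlation), with its call lost without 4 of the 6 libraries at edgeR adjusted p of up to 0.0985. QQS was the member called of 2 silenced loci (camera adjusted p = 0.000334). The other, ATLINE1-4, had no count in either group, so this list test rests on QQS alone. FUS3, with 1 count in hda9-1 h2a.z-5, was the member called of 3 seed maturation genes, against 2 adjusted over the list alone (camera adjusted p = 0.00144). Both lists passed with an estimated correlation (adjusted p = 0.0467 and 0.0492), though not with the block as well (0.212 for both), and the FUS3 call was lost without each of the 6 libraries, with edgeR adjusted p of up to 0.134. The target genes had HDA9 lower in both ways (camera adjusted p = 1.49e-08). HTA4 was called with replicate number as a block (edgeR adjusted p = 0.0466) and not without it. The photosynthesis list had camera adjusted p = 0.0598, and 0.0163 with replicate number as a block. The total of 133 was 1570 with replicate number as a block, 46, 59 and 33 without h2a.z-5 replicates 1, 2 and 3, and 65 without hda9-1 h2a.z-5 replicate 3. Against hda9-1, 132 genes were higher and 64 lower. AGO5 rose from 0.0438 to 2.27 ± 1.73 CPM, AT4G18900 rose by 4.59 ± 0.45 log2 units, and SADHU5-1 fell by 4.997 ± 0.51. SEP2 was the member called of 11 floral organ and meristem genes, against 7 adjusted over the list alone (camera adjusted p = 4.48e-06, and adjusted p = 0.380 with an estimated correlation). NUDT6 fell of 24 salicylic acid defence genes, and 2 adjusted over the list alone (camera adjusted p = 4.48e-06, and adjusted p = 0.486 with an estimated correlation). Both calls were lost without 4 of the 6 libraries, with edgeR adjusted p of up to 0.145 for SEP2 and 0.171 for NUDT6. The cell cycle list, with no member called, had camera adjusted p = 0.0378, and adjusted p = 0.705 with an estimated correlation. The jasmonate list had camera adjusted p = 0.0700, and 0.00638 with the block. Its genes lay 2.62 log2 units higher in hda9-1 h2a.z-5 replicate 3 than in the other replicates, and its median log2 fold change was -0.52 with this library and -2.19 without it (camera adjusted p = 7.43e-08). Target genes had 3 lower and 4 adjusted over the list alone (camera adjusted p = 2.05e-16). The HTA9 call, at a log2 fold change of -1.09, was lost without hda9-1 h2a.z-5 replicate 1 (edgeR adjusted p = 0.0601) and without hda9-1 replicates 1 (0.0797) and 2 (0.0857). The total of 196 was 870 with replicate number as a block, 96 without hda9-1 h2a.z-5 replicate 1, and 127, 57 and 80 without hda9-1 replicates 1, 2 and 3.

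Of the 164 genes higher in hda9-1 than in Col-0, 18 were also higher in hda9-1 h2a.z-5 than in h2a.z-5 (10.98%, exact 95% interval 6.64% to 16.8%), against 0.279% of all genes tested. The share was 26.95% with replicate number as a block, 21.1% and 23.5% without Col-0 replicates 1 and 2, and 18.18%, 25.9% and 20% without hda9-1 replicates 1, 2 and 3. It was 3.05%, 4.88% and 3.05% without h2a.z-5 replicates 1, 2 and 3, and 5.49% and 6.71% without hda9-1 h2a.z-5 replicates 1 and 3. The interaction of hda9-1 with h2a.z-5 called 7 genes, and 452 passed an unadjusted p of 0.05. AT3G29120 (3.85, edgeR adjusted p = 0.000136), AT2G05914, AT2G04080, AT4G04223, AT3G05945 and AT5G11330 were higher and AT1G75945 was lower (-8.53, edgeR adjusted p = 4.82e-08). The count was 4 without hda9-1 replicate 2 and 4 without replicate 3. The AT2G05914 call was lost without hda9-1 replicates 2 (edgeR adjusted p = 0.0609) and 3 (0.0546), and those of AT2G04080 and AT4G04223 without 10 and 11 of the 12 libraries taken singly (up to 0.160 and 0.165). Silenced loci, of which the median log2 fold change was -0.64 while the test pointed up, had camera adjusted p = 0.000215, and adjusted p = 0.0624 with an estimated correlation. Of the 2 members tested, ATLINE1-4 had no count in Col-0, h2a.z-5 or hda9-1 h2a.z-5. It was at 0.0452 ± 0.0783 CPM in hda9-1, so its value in this interaction rests on traces. The jasmonate list had camera adjusted p = 0.119, and 0.00345 with the block; it was 4.29e-08 without Col-0 replicate 3 and 1.39e-08 without hda9-1 h2a.z-5 replicate 3, where its genes were high.

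TEs changed in far smaller numbers where HDA6 was not targeted. In h2a.z-5, 6 TEs were higher and 8 lower than in Col-0. AT1TE93275 was at 17.0 ± 3.78 CPM against 0.0729 ± 0.0413 CPM (SD, n = 3), levels like those of the gene AT1G75945, and AT4TE03410 fell from 29.0 ± 6.28 to 1.40 ± 0.596 CPM, like SADHU5-1; these are probably the same reads. AT2TE06165 had no count in Col-0 and was at least 83.5-fold higher. In hda9-1, 7 TEs were higher and 18 lower; AT3TE30970 rose by 2.73 log2 units (edgeR adjusted p = 0.000204) and AT2TE20630 fell by 4.11 log2 units (edgeR adjusted p = 0.000324). The libraries labelled hda6-1 h2a.z-5 had 171 TEs higher and 5 lower. In hda9-1 h2a.z-5, 10 TEs were higher and 24 lower. The interaction tests called 11 TEs (2 higher and 9 lower) for hda6-1 and 2 for hda9-1. Since the genotypes were fitted together, the zeros of hda6-1 replicate 1 entered these tests too. A fit that leaves this library out, chosen after the data were seen, gave 6 TEs higher and 12 lower in h2a.z-5, 16 and 24 in hda9-1, 24 and 50 in hda9-1 h2a.z-5 and 225 and 13 in the libraries labelled hda6-1 h2a.z-5, where 43, 54, 51, 24 and 53 of the higher lay on chromosomes 1 to 5. The total in h2a.z-5, 14, was 9 without Col-0 replicate 2, without h2a.z-5 replicate 1 and without h2a.z-5 replicate 3. In hda9-1 the total of 25 was 60 with replicate number as a block, 12, 13 and 4 without Col-0 replicates 1, 2 and 3, and 10 and 9 without hda9-1 replicates 1 and 3. In the libraries labelled hda6-1 h2a.z-5 the total of 176 was 104 and 114 without Col-0 replicates 1 and 3. In hda9-1 h2a.z-5 the total of 34 was 84 with the block, 16, 20 and 11 without Col-0 replicates 1, 2 and 3, and 21, 20 and 16 without hda9-1 h2a.z-5 replicates 1, 2 and 3. The 11 of the hda6-1 interaction were 7 without h2a.z-5 replicate 1.

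Several mutants had higher genes in common. All 109 genes higher in h2a.z-5 than in Col-0 were also higher in the libraries labelled hda6-1 h2a.z-5, against 5.22 for independent lists, and 73 were in hda9-1 h2a.z-5, against 2.92. These crosses carry h2a.z-5 themselves, so an excess over independent lists comes with the design. The libraries labelled hda6-1 shared 60 higher genes with h2a.z-5, against 3.22, and 18 with hda9-1, against 4.84. AT1G75945, AT3G21040, AT4G22390, AT5G35935, AT5G37450, AT5G55560 and AT5G60610 were higher in all 5 mutants than in Col-0. Each of these contrasts uses the same 3 Col-0 libraries, which were not split between contrasts, so part of the excess may come from the shared controls. In h2a.z-5 and hda9-1, 8 higher genes were shared, against 0.861. The contrasts were compared with simulated data in which no group changed and the replicate numbers had their fitted effects, a simulation chosen after the data were seen. The covariance of the log2 fold changes there was 0.0522 to 0.0614 over all pairs of contrasts and runs. In the planned simulation, without effects of the replicate numbers, the mean covariance was higher, at 0.0711 to 0.0744 over the pairs. For h2a.z-5 and hda6-1 the covariance there was 0.0717, and for hda6-1 and hda9-1 h2a.z-5 it was 0.0720, above the 0.0707 of the data. In the data, the covariance was 0.252 for h2a.z-5 and hda6-1 h2a.z-5, 0.221 for h2a.z-5 and hda9-1 h2a.z-5, and 0.196 for hda6-1 and hda9-1. For the last pair, some loci high in hda6-1 and without counts in Col-0 had traces in hda9-1. Among these, AT1G53810 was at 0.280 ± 0.486 CPM and AT2G23490 at 0.244 ± 0.423 CPM (SD, n = 3), each with an SD above the mean. Neither had a count in hda9-1 h2a.z-5. Traces in few libraries can raise the covariance, and their part in it was not tested. The data gave 0.0812 for h2a.z-5 and hda6-1 and 0.0374 for h2a.z-5 and hda9-1. They gave 0.0707 for hda6-1 and hda9-1 h2a.z-5, which shared 74 higher genes against 16.4.

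TSA was compared with Mock to ask what inhibiting deacetylases changes in the wild type. Seed storage and maturation genes rose: EM1, a late embryogenesis gene, was at 20.9 ± 25.3 CPM against 0.0567 ± 0.0530 CPM (SD, n = 5), OLEO1, an oil body protein gene, at 19.0 ± 14.2 CPM against 0.3002 ± 0.394 CPM, and ABI3, a regulator of seed maturation, at 4.195 ± 2.90 CPM against 0.120 ± 0.0926 CPM. Of the 17 genes of this list 12 were tested. All 12 rose, also adjusted over the list alone (camera adjusted p = 1.95e-06, and adjusted p = 0.830 with an estimated correlation), and 11 kept the call whichever library was left out. Genes near 0 in Mock pass the filter only through counts in TSA, so a rise is favoured among the genes tested. Phosphate starvation genes fell, 9 of 15 with 1 higher, and 10 with 1 higher adjusted over the list alone (camera adjusted p = 1.89e-05, and adjusted p = 0.793 with an estimated correlation). The noncoding RNA gene IPS1 fell from 139 ± 64.8 to 1.86 ± 1.21 CPM, and MGD3, a galactolipid synthase gene, from 113 ± 49.1 to 7.26 ± 2.72 CPM; all 9 kept the call whichever library was left out. CSY1, a citrate synthase gene, had no count in Mock and was at least 2189-fold higher. The noncoding RNA gene AT2G08820 fell from 46.4 ± 10.5 to 0.397 ± 0.329 CPM. HTA8 rose from 4.86 ± 1.04 to 20.1 ± 5.91 CPM and HDA6 rose by 1.09 ± 0.21 log2 units, while HTA4 (AT4G13570) fell by 3.36 ± 0.35 log2 units; HTA9 (edgeR adjusted p = 0.852) and HTA11 (0.830) did not pass. In all, 3736 genes were higher and 3379 lower of 20201 tested.

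No other list passed the camera test between TSA and Mock. Counts of higher and lower members follow, with those adjusted over the list alone given where they differ. Histone deacetylase and acetyltransferase genes had 6 higher and 4 lower of 19 (camera adjusted p = 0.624); HD2C rose by 1.31 and HDA19 by 1.07 log2 units, and HAC12, an acetyltransferase gene, fell by 0.99. Flowering time genes had 1 higher and 5 lower of 14, and 1 and 6 adjusted over the list alone (0.0780); SOC1, a promoter of flowering, fell by 2.70 ± 0.39 log2 units (edgeR adjusted p = 0.000560), and FT, the mobile flowering signal, stood at 0.0112 CPM against 1.32 CPM. Salicylic acid defence genes had 7 higher and 2 lower of 24 (0.181), 5 of which kept the call whichever library was left out, among them PR2 (3.02 ± 0.46) and ICS1 (1.18). Jasmonate genes had 4 higher of 17 (0.0780), of which CORI3 (3.90) kept the call whichever library was left out. Anthocyanin and flavonoid genes had 6 higher and 1 lower of 15, and 7 and 1 adjusted over the list alone (0.0872), of which TT7 and TT8 kept the call. Cell cycle genes had 5 higher of 12 (0.101), with CYCB1;1, CDKB2;1 and PCNA1 kept, and xenobiotic response genes had 5 higher and 3 lower of 16 (0.881), with CYP81D8 higher by 3.09 and CYP81D11 lower by 5.83 log2 units. Cold and drought response genes had 4 higher and 1 lower of 17 (0.576), with a median of -0.11 where the test pointed up, and HAI1, LEA7 and RD29B kept. Circadian clock genes had 1 higher and 4 lower of 18 (0.342), with TOC1 and LNK2 kept. Senescence genes had SAG13 and SAG29 higher of 12 (0.101), auxin response genes GH3.3 and GH3.5 of 7 (0.832), of which GH3.5 lost the call without 5 single libraries (edgeR adjusted p of 0.0522 to 0.0619), and root markers 2 of 15 and 1 adjusted over the list alone (0.695). Heat shock genes had 3 lower of 14, and 1 adjusted over the list alone (0.201), photosynthesis genes 3 of 24 and 0 (0.379), and SWR1 and INO80 subunits 1 higher and 1 lower of 9, and 0 adjusted over the list alone (0.502). Without single libraries, the calls of 1 root marker, 2 of the 3 heat shock genes, 2 of the 3 photosynthesis genes, both SWR1 and INO80 subunits, SRT1 among the deacetylases and MAF3 among the flowering time genes were lost. Floral organ and meristem genes had AG higher and SEP3 and PI lower of 8 (0.379); target genes had 2 higher and 1 lower of 8 (0.881), and of the silenced loci QQS, tested alone, fell by 1.81 ± 0.30 log2 units.

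Replicate 5 of both groups stood apart. The morning-phased clock gene LHY was at 664.5 ± 56.0 CPM (SD, n = 4) in Mock replicates 1 to 4 and at 6.80 CPM in Mock replicate 5, and at 259 ± 61.7 CPM and 10.04 CPM in TSA. CCA1, its close relative, was at 315 ± 28.5 CPM and 10.2 CPM in Mock and at 111 ± 41.9 CPM and 12.4 CPM in TSA. The clock-regulated RNA-binding protein gene CCR2 was higher in replicate 5, at 462.5 CPM in Mock and 1091 CPM in TSA. In Mock replicate 5, 2204 genes lay at least 2-fold above and 1932 at least 2-fold below all 4 other replicates, and in TSA replicate 5 it was 1233 and 714. Several lists moved with it: in Mock and TSA replicate 5, cold and drought response genes deviated by 3.40 and 2.27 log2 units, anthocyanin genes by -3.46 and -4.02 and auxin response genes by 1.77 and 2.33. Jasmonate genes deviated by 2.80 in Mock, but by -0.02 in TSA. With replicates 1 to 4 alone, an alternative chosen after the data were seen, 5481 genes were higher and 5478 lower. In these, the jasmonate list (15 higher, camera adjusted p = 1.35e-07), anthocyanin and flavonoid genes (11 higher and 1 lower, 0.000494), salicylic acid defence genes (14 higher and 4 lower, 0.00864), flowering time genes (1 higher and 8 lower, 0.0406), clock genes (4 higher and 10 lower, 0.0406) and senescence genes (7 higher and 1 lower, 0.0253) also passed, but none of them with an estimated correlation (adjusted p of 0.431 to 0.796). With all replicates and replicate number as a block, the camera adjusted p was 0.00675 for jasmonate genes, 1.09e-05 for anthocyanin and flavonoid genes, 0.0398 for flowering time genes, 0.0166 for senescence genes and 0.0499 for cell cycle genes, and with an estimated correlation none of these passed (adjusted p of 0.352 to 0.865).

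**Figure D4:**
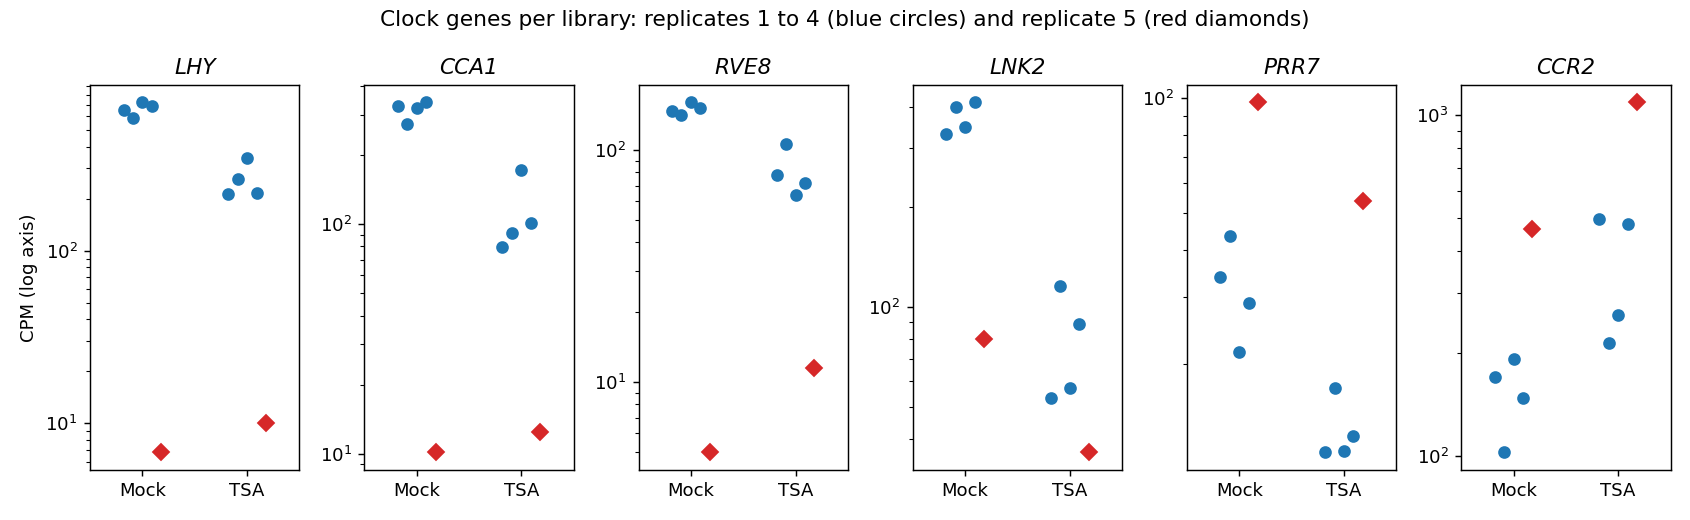
CPM (log axis) of 6 clock genes in each Mock and TSA library, with replicates 1 to 4 as blue circles and replicate 5 as red diamonds. LHY and CCA1 were lowest in replicate 5 of both groups, and CCR2 highest.

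The genes raised by TSA were followed in the mutants, to ask whether inhibitor and mutations move the same genes. The genotype libraries were grown and normalized apart from the Mock and TSA libraries. Of 2583 genes raised at least 2-fold by TSA, 2218 were tested in the genotypes, and their median log2 fold change was 0.17 in the libraries labelled hda6-1 h2a.z-5, 0.10 in h2a.z-5, 0.09 in those labelled hda6-1 and 0.09 in hda9-1. In fry, a test of whether a set moves one way, the adjusted p was 0.000995, 0.0434, 0.0400 and 0.0434 in that order, and 0.207 in hda9-1 h2a.z-5. In camera with an estimated correlation none of the 4 passed (adjusted p = 0.0808, 0.120, 0.257 and 0.210). With replicate number as a block the fry adjusted p was 0.00490 in the libraries labelled hda6-1 h2a.z-5 and 0.0561 in the other 3, and camera with an estimated correlation again passed in none (adjusted p of 0.310 or more). The 2210 tested genes lowered at least 2-fold by TSA had a median of -0.17 in hda9-1 (fry adjusted p = 0.0117), -0.12 in hda9-1 h2a.z-5 (0.0462), -0.11 in h2a.z-5 (0.0484), -0.12 in the libraries labelled hda6-1 h2a.z-5 (0.283) and -0.06 in those labelled hda6-1 (0.636). With the block, added after the data were seen, the fry adjusted p was 0.00240, 0.00783, 0.0114, 0.0809 and 0.488. In camera with an estimated correlation, hda9-1 alone of the 5 passed (adjusted p = 0.0462 without the block and 0.0498 with it). The overlaps below cover only genes tested in both tables, which leaves 219 of the 613 genes higher in the libraries labelled hda6-1. A gene without counts in Mock is tested there only if TSA libraries hold counts. Loci that stay silent in both thus drop out, which can raise the overlap. Fisher's test also takes genes as independent draws, so its p-values overstate the certainty where genes move together. Of the 219, 72 were among those raised by TSA, against 25.03 for independent lists (Fisher exact adjusted p = 1.01e-16). Of the same 219, 47 were lowered by it, against 24.9 (Fisher exact adjusted p = 4.29e-05). Of the 20 lower genes, 8 were lowered by TSA, against 2.28 (Fisher exact adjusted p = 0.00181). Of the 994 genes higher in the libraries labelled hda6-1 h2a.z-5, 611 were tested in both tables. Of these 611, 187 were raised by TSA, against 69.8 (Fisher exact adjusted p = 2.19e-37), and 86 were lowered by it, against 69.6 (0.0477). Of 250 lower genes there, 63 were lowered, against 28.5 (3.69e-09), and 18 raised, against 28.6 (0.0467). In h2a.z-5 31 of 72 higher genes were raised by TSA, against 8.23 (Fisher exact adjusted p = 4.06e-11), and 21 of 74 lower genes were lowered by it, against 8.43 (0.000117). AGO5 was among the genes higher in both, at 10.8 CPM in TSA and 0.272 CPM in Mock. In hda9-1 37 of 157 higher genes were raised by TSA, against 17.9 (Fisher exact adjusted p = 5.19e-05), and 67 of 182 lower genes were lowered by it, against 20.7 (Fisher exact adjusted p = 1.69e-18). In hda9-1 h2a.z-5, 83 of 493 higher genes were raised by TSA, against 56.3 (Fisher exact adjusted p = 0.000628), and 78 were lowered by it, against 56.1 (0.00385). Of 639 lower genes there, 179 were lowered by TSA, against 72.8 (9.41e-31), and 53 raised, against 73.0 (0.0161). With replicate number as a block, both overlaps of the higher genes of hda9-1 h2a.z-5 did not pass (0.288 and 0.491). With no minimum fold for TSA they did not pass either (0.247 and 0.245), nor did that of the higher genes of hda6-1 h2a.z-5 with those lowered by TSA, which turned to 95 against 105.2 (0.307).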

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

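All tests reported here on technical and biological explanations, and the other splits of the libraries, were chosen only after the results were seen. HDA6 was the first pattern weighed: its transcript was about 7.68 times the Col-0 level in the libraries labelled hda6-1 and at the Col-0 level in those labelled hda6-1 h2a.z-5, with an interaction of -3.15 log2 units. An exchange of these labels was excluded, since the lowest HTA11 level of the libraries labelled hda6-1 was 55.0 CPM, far above those labelled hda6-1 h2a.z-5. Full HDA6 function in the latter predicted a share of genes rising again like that of all genes. This prediction failed. Of the genes raised in the libraries labelled hda6-1, 49.9% rose again on the h2a.z-5 background, against 2.01% of all genes. The prediction assumes that raised genes fall back once HDA6 function is present, which was not tested, so full function is not excluded. The interaction of -3.15 could come from a dependence of the raised transcript on H2A.Z, or from another HDA6 allele in the cross, and the data cannot tell these apart. Read sequences over HDA6 would be needed.

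The second pattern was replicate 5 of Mock and of TSA. Of 18 clock genes, 17 deviated in the same direction in replicate 5 of both groups, in line with a harvest at another time of day; GI was the exception. More root tissue was excluded for Mock replicate 5, where root markers deviated by a median of -0.32 log2 units with an upper quartile of 0.52, under the 1 that was asked for, and remained possible for TSA replicate 5, where the median was 2.60. No biological explanation was tested, since the design gives none.

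The third pattern was the TE counts of hda6-1 replicate 1. After AT4TE59920, 0 of 7134 TEs had a count in this library, which suggests that its column ends early. Silence of chromosome 5 in this library was excluded, since 15.02% of its pseudogene counts in the gene table came from chromosome 5, against 15.8% and 14.0% in replicates 2 and 3.

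The other results in this paragraph stand out because 1 library lay far from the other 4 of its group, by the ratio of its gap to the range of the group, among 144 groups of named genes. Chance alone would pick about 1 group in 20, or 7.2, and 19 were picked, 15 of them through replicate 5; groups of 3 libraries were not tested. In Mock, the ratio was 0.772 for EDS5 (replicate 5, 23.0 CPM against at most 11.5), 0.853 for MGD3 (replicate 5, 26.0 CPM against at least 126), 0.931 for GH3.3 (replicate 5, 53.8 CPM against at most 7.57) and 0.822 for OLEO1 (replicate 3, 0.994 CPM against at most 0.195). Also in Mock, it was 0.759 for LNK2, 0.784 for LNK1 and 0.782 for CDKB1;1, all low in replicate 5, and 0.944 for AT1G71250, 1 for AT5G03820 and 1 for AT5G09370, where a single library differed by a count or so. In TSA, the ratio was 0.777 for TT8 (replicate 5, 0.906 CPM against at least 12.7), 0.751 for OPR2 (replicate 5, 10.1 CPM against at most 4.67), 0.836 for TOC1 (replicate 5, 44.9 CPM against at most 33.6) and 0.811 for AT5G09370 (replicate 4, 8.89 CPM against at most 1.96). It was 0.800 for AT3G46490, and 1 for each of MRU1, AT2G08825, PRB1 and AT5G35525, of which a single TSA library had counts.

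Differences between the backgrounds stood out by the interaction test. For hda6-1 with h2a.z-5, 11 genes and 11 TEs changed, among them HDA6 (-3.15), AT3G05955 (5.91), AT3G05945 (4.53), AT3G29120 (3.96), AT1G18193 (3.86), AT1G75945 (-8.21), AT3G29633 (-5.51) and AT1G67105 (-4.35). The median log2 differences of the lists that passed were -0.0324 for target genes, -0.0867 for histone deacetylases and acetyltransferases, 0.97 for jasmonate genes (-0.46 without Col-0 replicate 3, where these genes lay 2.31 log2 units above those of the other replicates), -0.28 for photosynthesis genes, 0.63 for floral organ and meristem genes and 0.57 for xenobiotic response genes. For hda9-1 with h2a.z-5, 7 genes and 2 TEs changed, among them AT3G29120 (3.85), AT2G05914 (3.02), AT2G04080 (2.50), AT4G04223 (2.46) and AT1G75945 (-8.53). The median was -0.33 for salicylic acid defence genes, -0.64 for silenced loci, 0.76 for xenobiotic response genes (0.16, with camera adjusted p = 0.187, without hda9-1 h2a.z-5 replicate 3) and -0.15 for the genes raised by TSA. In camera with an estimated correlation, the target genes of the hda6-1 interaction (adjusted p = 0.0337) and the genes raised by TSA of the hda9-1 interaction (0.0346, and 0.2175 with replicate number as a block) also passed. The genes lowered by TSA moved the other way in the hda9-1 interaction, with a median of 0.17. They passed the same test without the block (camera adjusted p = 0.045) and with it (0.044). AT1G75945 was at 11.2 CPM or more in every mutant group, so that a sum of single changes overshoots its level in the crosses.

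The libraries were also split into other groups of the same size. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real grouping alone (1 of 10) called as many genes in each of the 9 such gene contrasts and as many TEs in each of the 5 such TE contrasts. The highest other count of genes was 0 against 189 for h2a.z-5, 0 against 634 for hda6-1, 9 against 363 for hda9-1, 0 against 1248 for hda6-1 h2a.z-5 and 1 against 1224 for hda9-1 h2a.z-5, each with Col-0. Against h2a.z-5 it was 0 against 420 and 0 against 133 for the crosses with hda6-1 and hda9-1, against hda6-1 it was 0 against 469, and against hda9-1 it was 118 against 196. For TEs it was 0 against each of 14, 283, 25, 176 and 34. Besides the real grouping, 3 splits part every pair of libraries with the same number, and these called 0 genes with edgeR in each contrast. For TSA, 1 of 100 splits called as many as the real 7115, and the highest other was 590. Among the 13 other splits that part every pair, the highest was 388. Since the numbers pair the samples, these 13 are the like reference. They are too few for a share under 0.05, so the splits do not exclude chance. For the gene interactions, 2 of 40 splits called at least as many genes as the real 11 and 7. The highest others, 456 and 608, are many times the real counts. For the TE interactions, 1 of 28 splits called as many as the real 11 for hda6-1 (highest other 2), and 4 of 28 as many as the real 2 for hda9-1 (highest other 7). By these counts alone chance was excluded for the TEs of hda6-1 only. Labels exchanged among 4 genotypes, however, carry the changes of single genotypes into the interaction, and 39 added draws that part every pair gave up to 23 and 1372 genes and 312 and 10 TEs. Such draws are no reference without change, so they do not settle whether chance gave the interaction counts.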

How the results depend on the processing

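Tests with added alternatives (replicates 1 to 4, no rRNA genes, TEs up to the point where hda6-1 replicate 1 ends, a TE fit that leaves this library out, protein-coding genes only) were chosen only after the results were seen. Of the named genes in the genotype and TSA contrasts, 225 of 228 kept their call with DESeq2, 227 of 229 with RLE size factors, 226 of 229 without a filter, 122 of 163 with the groups of the contrast only, 228 of 229 with the replicate block and 62 of 62 in TSA with replicates 1 to 4; none reversed. The block ended 2 named calls and added 2, given beside those results, and changed no other named call. With 3 libraries a group, leaving out 1 leaves fewer samples, which the counts below reflect. The fits without single libraries also had no replicate block. With simulated data at the design of the genotypes, 38.8% of 2-fold and 74.2% of 4-fold changes were called, and for TSA 4.48% and 42.4%. Small changes were thus often missed in the simulation. On the same simulated TSA counts DESeq2 called 31.3% and 75.8%, with 36 false calls against 3. Each fold was given to at most 67 genes, far fewer than the 7115 called for TSA, so these shares need not hold there. Why the counts moved under the other settings was not examined: the cause was not tested.

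With DESeq2, changed genes numbered 388 for h2a.z-5, 1205 for hda9-1 and 2070 for hda9-1 h2a.z-5 against Col-0, 563 for hda9-1 h2a.z-5 against h2a.z-5, 423 against hda9-1, and 30 and 14 for the hda6-1 and hda9-1 interactions. DESeq2 gave 27 TEs for h2a.z-5, 61 for hda9-1, 87 for hda9-1 h2a.z-5, and 32 and 4 for the interactions. With a log2 fold change of at least 1, 173 genes changed for hda9-1 and 607 for hda9-1 h2a.z-5 against Col-0. Without a filter it was 213 genes for hda9-1 and 11 for the hda9-1 interaction, and TEs numbered 31 for h2a.z-5, 503 for hda6-1, 44 for hda9-1, and 28 and 5 for the interactions. With the groups of the contrast only, which leaves 4 residual degrees of freedom, it was 61 genes for h2a.z-5, 53 for hda9-1 and 82 for hda9-1 h2a.z-5 against Col-0, 5 for hda9-1 h2a.z-5 against h2a.z-5 and 17 against hda9-1, and 56 TEs for hda9-1.

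With replicate number as a block, changed genes numbered 785 for h2a.z-5, 1005 for hda6-1, 3392 for hda9-1, 2988 for hda6-1 h2a.z-5 and 4922 for hda9-1 h2a.z-5 against Col-0. Against h2a.z-5 it was 671 and 1570 for the crosses with hda6-1 and hda9-1, against hda6-1 1049, against hda9-1 870, and 18 and 14 for the interactions. TEs with the block numbered 60 for hda9-1 and 84 for hda9-1 h2a.z-5. For TSA, replicates 1 to 4 gave 10959 genes, and 11320 with the block. TEs up to the point where hda6-1 replicate 1 ends numbered 46 for hda9-1, 68 for hda9-1 h2a.z-5 and 19 for the hda6-1 interaction, where fewer TEs were tested. A fit that leaves out this library gave 40 TEs for hda9-1 and 74 for hda9-1 h2a.z-5. With an estimated correlation 14 of 239 list tests passed, against 48 with the preset one. By fry, genes raised by TSA moved as a set in 7 genotype contrasts, upward in all of these but the hda9-1 interaction. Of the 7, only that interaction passed in camera with an estimated correlation (adjusted p = 0.0346). By fry the set moved in 1 contrast with no minimum fold, in 3 with TSA replicates 1 to 4 and in 1 with the block. The share for hda6-1 was 54.4% with DESeq2, and the share for hda9-1 was 17.81% with a log2 fold change of at least 1, 20.6% with DESeq2 and 26.95% with the block. TMM from the TE counts shifted the median log2 fold change of TEs in hda6-1 by -0.10, with 254 called.

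Leaving out 1 library at a time gave, lowest to highest, 95 to 135 genes for h2a.z-5, 551 to 592 for hda6-1, 53 to 257 for hda9-1, 825 to 1065 for hda6-1 h2a.z-5 and 419 to 1286 for hda9-1 h2a.z-5 against Col-0. The range was 248 to 333 and 33 to 138 for the crosses against h2a.z-5, 290 to 393 against hda6-1 and 57 to 286 against hda9-1. For the interactions it was 8 to 12 and 4 to 8, and for TSA 5604 to 8896. TEs ranged from 9 to 16 for h2a.z-5, 289 to 349 for hda6-1, 4 to 19 for hda9-1, 104 to 143 for hda6-1 h2a.z-5 and 11 to 21 for hda9-1 h2a.z-5, and from 7 to 11 and 2 to 3 for the interactions. The share was 33.6% to 51.5% for hda6-1 and 3.05% to 25.9% for hda9-1.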

Other observations

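The results described here were looked at only after the data had been seen, and no tests of an explanation were run on them. Ribosomal RNA genes took 0.433% to 1.32% of the counts in the Mock libraries and 1.32% to 5.15% in the TSA libraries. Without them 7170 genes were called between TSA and Mock, against 7115 with them. Of the 12 genes next to HDA6 on its chromosome, 3 were not tested and the others were not called in the libraries labelled hda6-1; the largest log2 fold changes were 0.37 for LOB and -0.38 for AT5G63080.

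AT1G75945 was near 0 in Col-0 on soil (0.0624 CPM), Mock (0.185 CPM) and TSA (0.140 CPM), and at 11.2 to 27.7 CPM in the 5 mutant groups, whether or not the label carries h2a.z-5. The pseudogene AT3G29120 was low in h2a.z-5 alone, at 0.444 CPM. AGO5 was at 18.9 CPM in the libraries labelled hda6-1 h2a.z-5, above the 6.29 CPM of h2a.z-5. Among the genotype libraries, hda9-1 h2a.z-5 replicate 3 had 576 genes at least 2-fold above and 379 at least 2-fold below both other replicates. Its jasmonate genes lay 2.62 log2 units above theirs, and those of Col-0 replicate 3 lay 2.31 above.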
